A study of Mus musculus with 2 samples.

How the data were processed

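Wound skin of db/db mice was dissociated per the labels' protocols with collagenase IV and deoxyribonuclease I for 1.5 h at 37 °C, passed through a 40 μm strainer and depleted of erythrocytes, and libraries were made with a SeekOne Digital Droplet 3' kit and sequenced on an Illumina NovaSeq. The deposited values are counts, namely whole numbers of UMIs per gene and cell barcode that the authors did not normalise, 1 matrix per library. The submitters' processing notes name STAR 2.7.2a, featureCounts, Subread 2.0.1 and the mm10 build, without saying which step each served. The annotation release and the way cells were called are not given in the sources used here. The lowest barcode total in each file was 500 UMIs, so barcodes below that were removed before deposit, and this limit bears most on cells with little RNA such as neutrophils. The labels give 1 library per group and do not say whether it came from 1 animal or several. Groups were taken from the treatment label of each sample. The depth was 90221152 UMIs for the PBS control and 100854857 for TSeL+L.

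Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 309 and 61 barcodes of the control for genes and mitochondrial share and 153 and 67 of TSeL+L. Scrublet, run per library in scanpy 1.11.5, marked 1 and 3 cells (0.01% and 0.02%) and so did not work. By a rule set for that case before the data were examined, the 5% of cells with the highest doublet scores were removed from each library, 648 and 839 cells, so doublets are thinned out and not identified. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes chosen in each library and combined (without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor variable and sex genes), 30 principal components, a shared-neighbour graph of 15 neighbours (edges under 0.067 dropped) and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1.0) gave 37 clusters over both libraries. The libraries were not integrated, so a cluster held mostly by 1 library may reflect that library and not a cell type.

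Clusters were named from 29 marker lists fixed before the data were examined, and all names mean cells that resemble the type. The scoring rule was set after the data were seen, and earlier versions of it were tried and dropped. A list's score was the mean log2 ratio of its markers over the median cluster, with an offset of 10 CPM, and a list counted only with at least 3 markers detected in a share of at least 0.1 of the cells. Subtypes were joined into classes. A cluster stayed unnamed if the next class reached over 0.5 of the best score, or if its median UMI count relative to its library was under 0.333 with no marker of its class among its 10 leading genes. This left 7 clusters unnamed, with 7.08% of control and 23.7% of TSeL+L cells. No cluster of a compared class had more markers of another class than of its own among its 10 leading genes against other classes. Shares have exact Clopper-Pearson 95% intervals.

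For the 5 classes with at least 100 cells in each library, UMIs were summed per library and class and expressed per 1000000 UMIs of the class total (CPM), with exact Poisson intervals. The ratio of TSeL+L over control has an exact conditional binomial interval. A count of 0 was set to a floor of 3 UMIs, while counts of 1 to 3 kept their ratio and interval, a change from the plan to treat both as the floor. Where the median gene with at least 20 UMIs in each library moved by over 0.1 on the log2 scale, log2 ratios were given relative to it, which applied to neutrophils and phagocytes, while CPM values are always of the class total. For neutrophils, where the shift of 0.86 changes which list members pass the 1.5-fold limit, counts are given on both scales. The shift of 0.11 in phagocytes also changes some counts, which are given on both scales for some lists only. With 1 library per group no test was possible. UMIs of 1 cell are not independent draws of the condition, so intervals cover counting error only.

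The genes named by size were chosen by a rule fixed before the data were examined: at least 50 UMIs over both libraries in the class, at least 50 CPM in the higher library, a class CPM of at least 0.5 times that of the whole library (a guard against free RNA from other cells), and no marker of another class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, receptor variable, predicted and sex genes were also left out. The 5 highest and 5 lowest by the interval bound nearest 0 were named in each class, 50 in all and 46 different genes. Some genes that these rules name are not reported here, and they were left out of the alternatives for single genes and of the figure. Members of the gene lists with at least 50 UMIs and the largest changes were named as well. A few further members (such as Gzmb and Igf1) and genes outside the rule (S100a9, Col1a1) were chosen after their values were seen.

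The 36 gene lists were fixed before the data were examined and hold 409 genes, 3 of them missing from the files under that symbol. In each class a member was measured with at least 20 UMIs over both libraries, and counted as higher or lower with a change of at least 1.5-fold and an interval that excludes 1. The list median was placed among medians of 10000 random lists of the same size drawn from bins of about 100 genes of similar expression, as a description of these libraries. Which of the lists were reported in which class, 39 pairs in all beside the antioxidant list in T cells and lists given as markers of other cells or of dissociation, and which of them lead each account, was decided after list values had been seen. Places of named genes were looked up by gene identifier in GENCODE vM21, whose build matches the notes; 154 of 154 identifiers were found.

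Simulated counts for the same genes and depths, with 200 genes changed by known folds, were used to check the ratios. In the phagocyte comparison (13304 genes) 42.1% of genes changed by 1.5-fold, 98.6% of those changed by 2-fold and 100% of those changed by 4-fold were recovered, in the endothelial comparison (5603 genes) 45.8%, 78.0% and 97.6%, and in the neutrophil comparison (8153 genes) 39.5%, 80.9% and 92.2%. Among unchanged genes 0.55%, 2.24% and 1.56% passed the same limits. The simulation holds counting error only.

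Alternatives fixed before the data were examined changed the filters, doublet removal, clustering resolution, principal components, scaling of genes within libraries, the scale of expression, the weighting of cells, thinning to 1000 UMIs, a subtraction of 5% of class UMIs as free RNA and the list minimum. Alternatives added after the data were seen named every cluster by its best list, gave clusters with at least 50 cells in each library the same weight in both, and left class markers out of lists. That weight was the cluster's share of the UMIs of these clusters over both libraries, so "equal cluster weights" means equal between libraries and not between clusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.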

Results

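The study used db/db mice on the C57BLKS/J background, a strain without a working leptin receptor that becomes obese and diabetic, whose skin wounds were infected with methicillin-resistant Staphylococcus aureus. The animals were randomised to phosphate-buffered saline (PBS control) or to a treatment labelled TSeL given with light irradiation (TSeL+L), and wound skin was taken on day 15 with dermis and epidermis kept together. Droplet-based 3' single-cell RNA sequencing gave 1 library per group. The PBS control library held 13339 cell barcodes with 90221152 unique molecular identifiers (UMIs), and the TSeL+L library held 17008 barcodes with 100854857 UMIs, over 32285 genes in each. After filtering, 12321 control cells (median 5372 UMIs and 1351 genes) and 15949 TSeL+L cells (median 4635 UMIs and 1713 genes) remained. With 1 library per group there was no replicate and no test between groups, so each value below describes these 2 libraries, and every interval (95%) covers counting error only.

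The cellular makeup of the wounds was compared between the libraries. Neutrophil-like cells, the granulocytes that arrive early at infected wounds, made up 42.4% of control cells (exact binomial interval 41.5 to 43.3, 5222 cells) and 8.06% of TSeL+L cells (7.64 to 8.49, 1285 cells). Fibroblast-like cells, which make the dermal matrix, made up 13.03% (12.4 to 13.6) and 28.4% (27.7 to 29.1). T cell-like and innate lymphoid-like cells made up 4.11% (3.76 to 4.47) and 8.03% (7.61 to 8.46), and endothelial-like cells 1.18% (1.00 to 1.39) and 1.75% (1.55 to 1.96). Mononuclear phagocyte-like cells (monocytes, macrophages and dendritic cells) stood at 31.5% (30.7 to 32.4) in the control and 28.7% (28.0 to 29.4) in TSeL+L.

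Rarer classes were mural-like cells, the contractile cells around vessels, at 0.0730% and 0.539%, mast-like cells at 0.333% and 0.608%, basophil-like cells at 0.235% and 0.0815%, and 5 and 11 skeletal muscle-like cells. Because a lower share of neutrophils raises all other shares, the classes were also expressed as shares of the named cells without neutrophils. On that scale mononuclear phagocytes held 62.4% (61.2 to 63.6) of 6227 control cells and 42.1% (41.2 to 43.0) of 10878 TSeL+L cells. Fibroblasts held 25.8% and 41.7%, T and innate lymphoid cells 8.13% and 11.8%, and endothelial cells 2.34% (1.98 to 2.75) and 2.56% (2.28 to 2.88), whose intervals overlapped. No cluster was keratinocyte-like. At least 3 basal keratinocyte markers were found in 0 control cells and 6 TSeL+L cells. For 0 of 12321 cells the share is 0.0243% with 0 set to 3, and the exact interval reaches 0.0299%. At least 3 markers of differentiated keratinocytes were found in 12 and 193 cells, which is no count of keratinocytes. Dmkn and Sbsn were leading genes of fibroblast-like clusters 5 (17 and 1286 cells) and 14, Krtdap also of cluster 14, and differentiated keratinocyte was the second list of both, at 0.35 and 0.401 of the best score. Clusters without a name held 7.08% of control cells and 23.7% of TSeL+L cells, with median depths of 1039 and 940.5 UMIs. With cells required to hold at least 1000 UMIs and 500 genes, the phagocyte difference changed sign, from -2.82 to 1.94 percentage points. With every cluster given its best-scoring name the fibroblast difference went from 15.4 to 30.5 points.

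**Figure D1:**
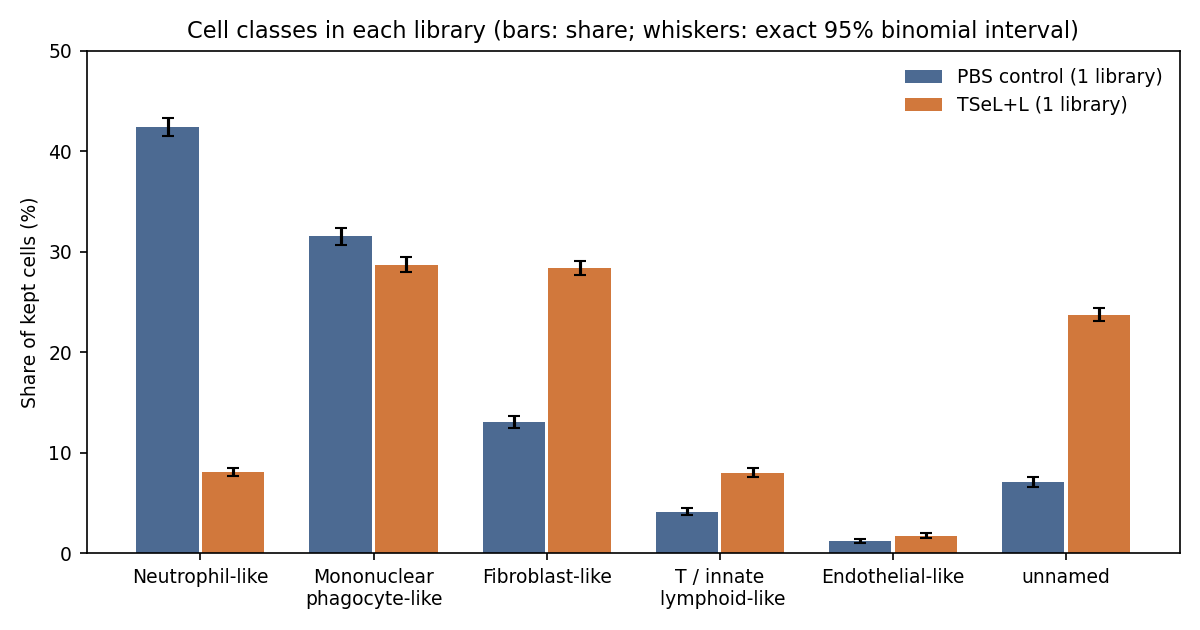
Share of kept cells (%, from 0) in each class for the PBS control and TSeL+L libraries, 1 library each, with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells stood at 42.4% and 8.06%, fibroblast-like cells at 13.03% and 28.4%, and unnamed cells at 7.08% and 23.7%.

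Within neutrophil-like cells of the TSeL+L library, genes of glycolysis and hypoxia were lower and antioxidant genes higher, on class totals and relative to the median gene. The median gene of this class lay 0.86 higher on the log2 scale in TSeL+L, and log2 ratios here are relative to it. The same was done in phagocytes, where the shift was 0.11, and the shift was within 0.04 of 0 in the other classes. Nos2, the inducible nitric oxide synthase, was at 438 CPM in the control and 12.3 CPM in TSeL+L (log2 ratio -6.01, interval -6.63 to -5.46). F3, the tissue factor that starts coagulation, was at 1189.8 and 90.4 CPM (-4.58, -4.79 to -4.37), and Serpinb2, an inhibitor of plasminogen activators, at 1095 and 88.5 CPM (-4.49). Ereg, an epidermal growth factor family ligand, was at 317 and 13.2 CPM (-5.44), and Slc15a2, a peptide transporter, at 169 and 6.62 CPM (-5.53). These 5 were the lowest genes named by the fixed size rule. In cluster 6 alone, before the ratio was set against the median gene, Nos2 went from -5.15 to -4.53, Serpinb2 from -3.63 to -1.05, Ereg from -4.58 to -2.59 and F3 from -3.72 to -2.65.

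Of 16 measured genes of glycolysis and hypoxia, 14 were at least 1.5-fold lower with an interval that excluded 1 and none was higher (median -1.94, percentile 0 among 10000 random lists matched on expression). On class totals 10 were lower and 1 higher. Ldha, lactate dehydrogenase, had a log2 ratio of -3.20 and Bnip3, a mitochondrial target of hypoxia signalling, -3.10. Of 18 antioxidant genes, 11 were higher and 1 lower (median 0.64, percentile 100), and on class totals 16 and 1. Nqo1, a quinone reductase, stood at 2.30 and 43.5 CPM (3.39, 2.89 to 3.90) and Gclc, which serves the making of glutathione, at 18.9 and 166 CPM (2.28). Hmox1, the haem oxygenase, was at 277 and 456 CPM, which is -0.14 relative to the median gene. Only 10 of the 18 reached the free RNA guard, a class level of at least 0.5 times that of the whole library, and genes of other cell types were higher in the same cells. Col1a1, a fibroblast collagen, stood at 91.0 and 742 CPM, and 16 of 20 collagen and matrix genes (median 1.57) and 5 of 7 MHC class II genes (median 1.18) were higher. In cluster 6 alone, on class totals, Nqo1 went from 4.24 to 1.90, Gclc from 3.13 to 1.98, Ldha from -2.34 to -1.61 and Bnip3 from -2.24 to -1.31.

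Of 14 inflammatory cytokine genes and their regulators, 11 were lower and 1 higher relative to the median gene (median -1.25, percentile 9.43), and 5 lower and 1 higher on class totals (median -0.39). Among the lower genes were Il1a, coding for the alarmin interleukin-1 alpha, at 2966 and 414 CPM (-3.70; on class totals -2.84, and -1.90 in cluster 6 alone), and Il1b at 13808 and 6787 CPM (-1.88). Genes of oxygen radical production turned with the scale: 5 of 9 were lower and 1 higher relative to the median gene (median -0.78, percentile 14.7), and 1 lower and 1 higher on class totals (median 0.081). Genes of pattern recognition turned too, with 3 of 9 lower and 1 higher (median -0.44, percentile 54.1), and 2 lower and 4 higher on class totals (median 0.42).

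The granule and maturation list had 8 genes higher and 6 lower of 15, 2 of them markers of the class (median 0.78, percentile 99.98), and 9 higher and 3 lower on class totals. Its largest ratios came from proteins of early neutrophil precursors: elastase Elane (9.83 and 309.9 CPM) and myeloperoxidase Mpo (14.7 and 313 CPM), whose TSeL+L UMIs lay in 5 and 6 cells, with 79.7% and 81.5% of them in 2 cells. Mmp8, the neutrophil collagenase, was at 613 and 94.2 CPM (-3.56). The other genes named as highest were Piwil2 (1.58 and 57.2 CPM), Clec4n, the receptor dectin-2 (17.2 and 334 CPM), and Slc40a1, the iron exporter ferroportin (5.66 and 109 CPM). In cluster 6 alone, on class totals, Piwil2 went from 5.18 to 3.28, Clec4n from 4.28 to 1.32 and Slc40a1 from 4.26 to 2.60. Different clusters held the class: cluster 0 held 64.4% of control neutrophils (median 4052.5 UMIs over the class) and cluster 6 held 95.6% of those of TSeL+L (median 1464 UMIs). Cluster 6 had a median of 0.314 of the UMIs of its library, under the naming limit of 0.333, and kept its name because the marker Cxcr2 was among its leading genes. Without it TSeL+L would hold 56 neutrophils, too few to compare. In cluster 6 alone, with 67 control and 1229 TSeL+L cells and log2 ratios not set against the median gene, the list medians were -1.13 in place of 1.64 for granule genes, -0.20 in place of 0.42 for pattern recognition, -0.14 in place of 0.081 for oxygen radical production, -0.49 in place of -1.08 for glycolysis and 0.86 in place of 1.49 for antioxidant genes. The granule value gives no direction, since it is that of the member Siglecf, from 2 and 11 UMIs (interval -3.33 to 2.08), and 6 of the 15 members had fewer than 20 UMIs in cluster 6.

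Mononuclear phagocyte-like cells of the TSeL+L library held less RNA of inflammatory genes. The lists of alternative activation, lipid handling and antioxidant defence had medians above 0. Relative to the median gene, 4 of 12, 6 of 13 and 7 of 18 of their genes were higher, and on class totals 5, 6 and 10. Nos2 was at 471 CPM in the control and 67.2 CPM in TSeL+L (-2.92, -2.98 to -2.85), and Arg1, the arginase that competes for the same substrate, at 910.0 and 119 CPM (-3.04, -3.09 to -2.99). Retnla, a secreted protein induced by type 2 cytokines, was at 42.9 and 619 CPM (3.74, 3.66 to 3.82), and Hmox1, the haem oxygenase that degrades haem, at 405 and 1969.6 CPM (2.17, 2.15 to 2.20). The chemokine Ccl17, a ligand of CCR4, was at 14.98 and 94.2 CPM (2.54), with 78.6% of its TSeL+L UMIs in cluster 23. Nos2 and Arg1 were also among the leading genes of cluster 1, and Retnla of cluster 9. With equal cluster weights, and before the ratio was set against the median gene, Ccl17 went from 2.65 to 1.03, Nos2 from -2.81 to -1.78, Il1b from -1.87 to -1.02, Ptgs2 from -1.53 to -0.66, Il1a from -2.51 to -1.76, Ckap2l from -2.51 to -1.90, Wfs1 from 2.41 to 1.32 and Mgl2 from 3.15 to 2.03.

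Of 15 inflammatory genes, 12 were lower and 1 higher (median -1.01, percentile 0), including Il1b at 7683 and 2105 CPM (-1.98) and Ptgs2, the inducible cyclooxygenase, at 1851 and 642 CPM (-1.64). The classical activation list, which shares Nos2, Il1b and Ptgs2 with it, had 7 genes lower and 1 higher of 11 (median -0.98, percentile 0). The higher gene, Il12b, lay in 31 control and 87 TSeL+L cells, and with equal cluster weights its ratio turned to -0.52. Of 12 alternative activation genes, 4 of them markers used to name the class, 4 were higher and 2 lower (median 0.42, percentile 100; on class totals 0.53, and 0.29 with equal cluster weights). Besides Retnla, the lectin Mgl2 (0.896 and 7.97 CPM, 3.04) and the chemokine Ccl24 (2.11) were higher, while Arg1 was the lowest member. Antioxidant genes were higher in 7 of 18 and lower in 1 (median 0.52, percentile 100), with Gclc at 56.1 and 233 CPM (1.95) and Gclm, its partner subunit, at 46.8 and 138 CPM (1.45).

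Genes for clearing dead cells and handling lipid were higher in 6 of 13 and lower in 1 (median 0.44, percentile 99.99). They included Cd36, a scavenger receptor, at 468 and 1199 CPM (1.25), and the receptor kinase Axl at 12.03 and 39.3 CPM (1.60). The MHC class II list had 2 of 10 genes higher and none lower (median 0.47, percentile 99.7), with Cd74, the invariant chain, at 2917 and 4564 CPM (0.54). On class totals 5 of the 10 were higher and none lower (median 0.58). Chemokines for monocytes and lymphocytes moved both ways, 3 higher and 4 lower of 12 (median 0.29, percentile 99.6), with Ccl22 at 18.6 and 77.2 CPM (1.95, but 0.31 with equal cluster weights) and Ccl5 at 1354 and 522 CPM (-1.48). Glycolysis and hypoxia genes were lower in 12 of 16 and higher in none (median -0.79, percentile 0), and pattern recognition genes lower in 6 of 10 and higher in none (median -0.86, percentile 0). Interferon-gamma response genes were lower in 7 of 11 and higher in 1 (median -0.67, percentile 0), and type I interferon response genes lower in 5 of 14 and higher in 2 (median -0.41, percentile 0.160). Also among the highest genes were Ear2, an eosinophil-type ribonuclease (5.58 and 52.6 CPM), and Wfs1, coding for wolframin of the endoplasmic reticulum (13.5 and 71.9 CPM). Among the lowest were Slc15a2 (131 and 3.91 CPM, -5.18), Il1a (679 and 119 CPM, -2.62) and Ckap2l (91.9 and 16.1 CPM, -2.62). Ckap2l lies directly downstream of Il1a on the same strand of chromosome 2. Cluster 1 held 49.5% of control phagocytes and 22.5% of those of TSeL+L, where clusters 4 and 7 held 22.4% and 22.1%. The neutrophil gene S100a9 stood at 1524 and 113 CPM in this class, and how much of it is free RNA was not tested. Genes of other cell types were higher in the same cells. They were 4 of 4 haemoglobin genes (median 4.76, percentile 100), of which 4 reached the free RNA guard, and 17 of 20 collagen and matrix genes with 1 lower (median 1.61), of which only 2 reached it. In fibroblasts 1 of 4 haemoglobin genes was higher (median 0.18). Over the whole libraries the haemoglobin gene Hba-a1 stood at 0.965 and 11.2 CPM.

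**Figure D2:**
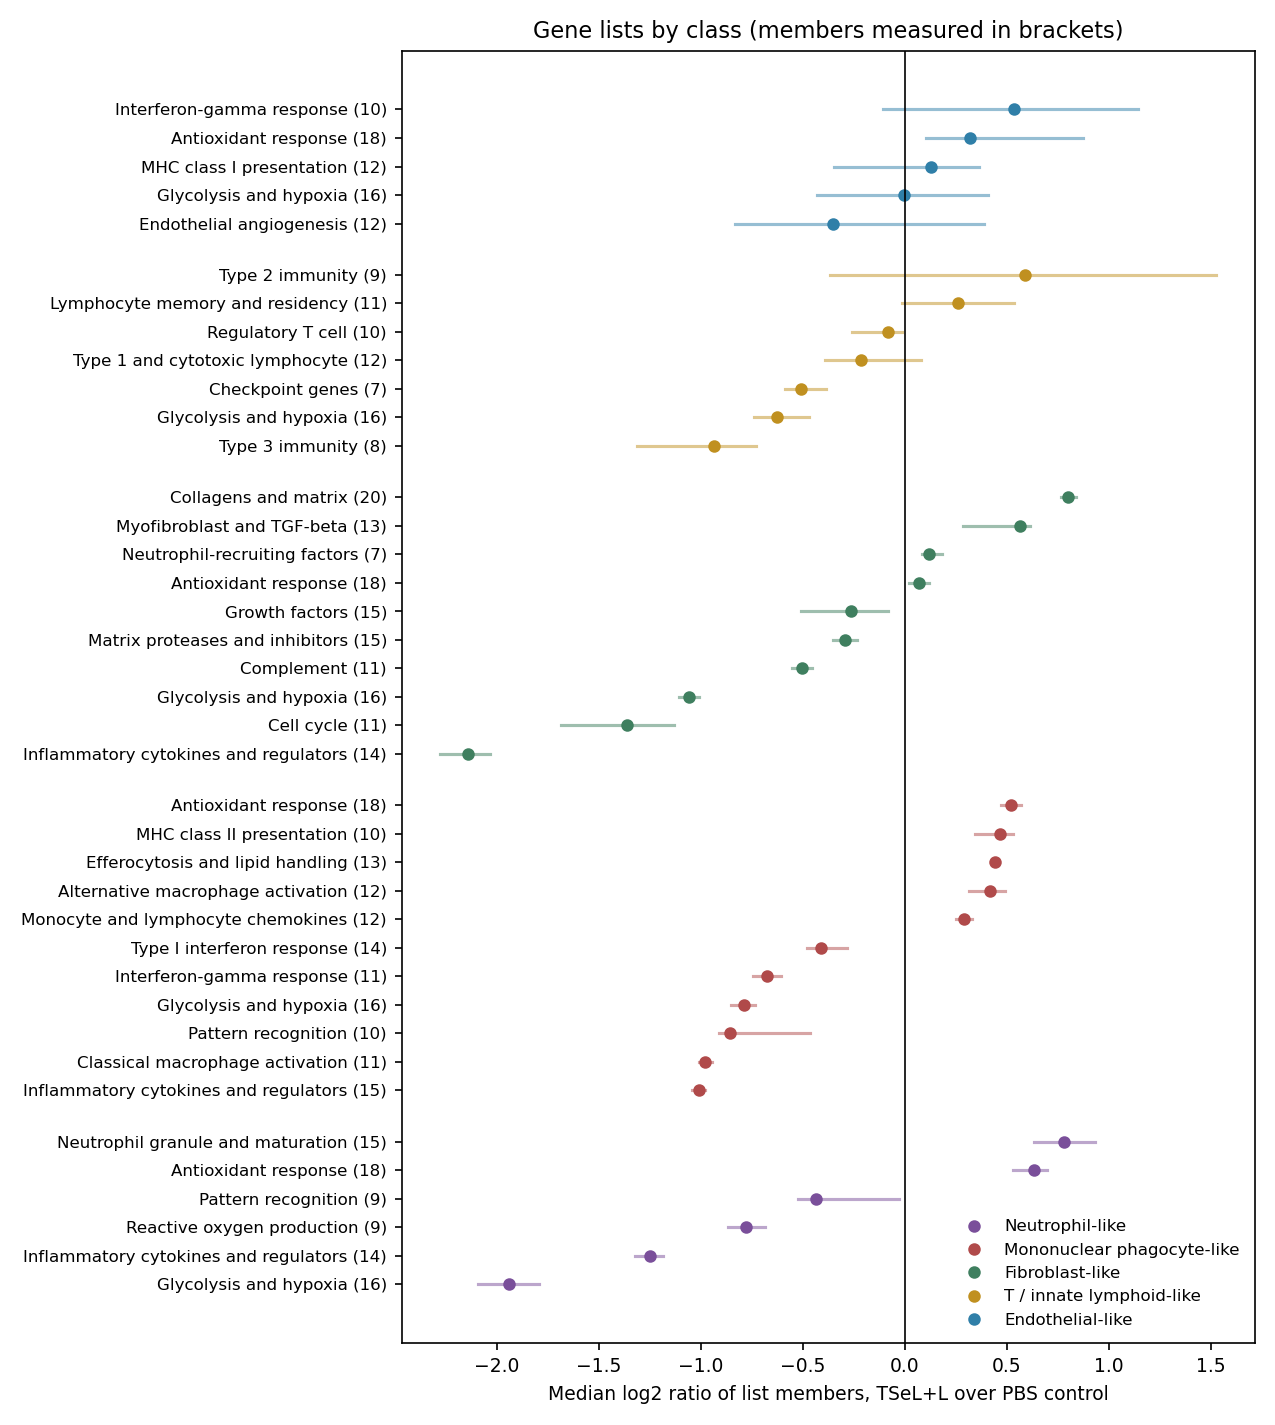
Median log2 ratio (TSeL+L over PBS control) of the measured members of 39 pairs of gene list and class, with the median of the members' 95% counting bounds as lines, and for neutrophils and phagocytes relative to the median gene of the class. Glycolysis and hypoxia genes lay at -1.94 in neutrophils, -0.79 in phagocytes, -1.06 in fibroblasts, -0.63 in T and innate lymphoid cells and -0.0041 in endothelial cells.

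Fibroblast-like cells of the TSeL+L library held more RNA of collagen and matrix genes, while Saa3, Lcn2, Hp, Saa1 and Reg3g were the lowest genes named by the size rule. Saa3, an acute-phase serum amyloid A protein, was at 22656 CPM in the control and 408 CPM in TSeL+L (-5.80, -5.82 to -5.78). Lcn2, the iron-withholding lipocalin, was at 1438 and 18.4 CPM (-6.29, -6.39 to -6.19) and Hp, the haemoglobin-binding haptoglobin, at 2048 and 28.4 CPM (-6.17). Saa1 was at 81.3 and 1.19 CPM (-6.09) and Reg3g, an antimicrobial lectin, at 621 and 25.9 CPM (-4.58). The genes with the largest ratios upward were Ptn, the growth factor pleiotrophin, at 9.45 and 157 CPM (4.05, 3.85 to 4.26), and the imprinted non-coding RNA H19 at 47.8 and 701 CPM (3.87, 3.78 to 3.96). With them were the matricellular gene Ccn3 at 14.1 and 132 CPM (3.23), the collagen VI chain gene Col6a6 at 6.44 and 55.4 CPM (3.11) and Dlk1, a Notch-family inhibitor of fat cell formation, at 9.22 and 65.5 CPM (2.83). H19, Ptn, Dlk1, Postn and Lrrc15 were leading genes of cluster 11, held mostly by TSeL+L, and Saa3, Hp and Reg3g of cluster 18, held mostly by the control. With clusters 3, 14 and 17 given the same weight in both libraries, the ratios were -4.76 for Saa3, -4.71 for Lcn2, -4.96 for Hp, -5.25 for Saa1 and -3.47 for Reg3g, and 2.86 for H19, 3.13 for Ptn, 2.35 for Ccn3 and 1.41 for Dlk1.

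Of 20 collagen and matrix genes, 13 were higher and 1 lower (median 0.80, percentile 99.99); 5 of the 20 were markers that named the class. Postn, coding for the matricellular protein periostin, stood at 615 and 1988 CPM (1.69, 1.67 to 1.72) and Fn1, fibronectin, at 664 and 1693 CPM (1.35), with ratios of 0.98 and 0.64 under equal cluster weights. The myofibroblast and TGF-beta list had 5 genes higher and 1 lower of 13 (median 0.56, percentile 99.8), with Lrrc15 at 26.5 and 123 CPM (2.22). Matrix proteases and their inhibitors moved both ways, 4 higher and 5 lower of 15 (median -0.29, percentile 0.245): Mmp3, stromelysin, was at 1346 and 626 CPM (-1.10, but -0.46 with equal cluster weights, under the 1.5-fold limit) and the inhibitor Timp2 at 642 and 1759.9 CPM (1.45). Growth factor genes were higher in 2 of 15 and lower in 4 (median -0.27, percentile 0.440), with Pgf, a vascular growth factor, at 78.5 and 15.01 CPM (-2.39, but -1.41 after thinning) and Igf1 at 95.95 and 165 CPM (0.78, but 0.58 with equal weight per cell, just under that limit).

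Complement genes were lower in 5 of 11 and higher in none (median -0.50, percentile 0.165), with C3 at 1555 and 760.3 CPM (-1.03, but -0.50 with equal cluster weights, under the 1.5-fold limit) and Cfb, factor B, at 427 and 153 CPM (-1.48). Cell cycle genes were lower in 10 of 11 and higher in none (median -1.36, percentile 0), including Top2a, a topoisomerase of dividing cells, at 21.2 and 3.39 CPM (-2.64), with 83.4% of its control UMIs in cluster 18 and a ratio of -0.36 with equal cluster weights. Glycolysis and hypoxia genes were lower in 11 of 16 and higher in none (median -1.06, percentile 0), though only 5 of the 16 reached the free RNA guard. The inflammatory list had 9 genes lower and none higher of 14 (median -2.14, percentile 0), of which only 4 reached that guard. After a subtraction of free RNA the median was -4.75, with Il1b at -11.2 and Ccl3 at -11.7. Counts that the subtraction took to 0 were set to 3 UMIs, so these values do not measure the size of a change. RNA of neutrophil genes was lower in the same cells: S100a9 stood at 1541 and 61.5 CPM, S100a8 at 1290 and 49.8 CPM, and 8 of 13 granule and maturation genes were lower and none higher (median -1.33). The antioxidant list had 6 genes higher and 3 lower of 18 (median 0.070, percentile 40.2): Hmox1 stood at 91.97 and 496 CPM (2.43, 2.37 to 2.50, but 1.63 with equal cluster weights) and Gclm at 19.4 and 85.7 CPM (2.14), while the metallothionein Mt1 stood at 9289 and 3514 CPM (-1.40). The neutrophil-recruiting factors had 1 gene higher and 1 lower of 7 (median 0.12, percentile 57.5), namely Csf2 at 122 and 305 CPM (1.32, but 0.17 with equal cluster weights) and Csf3, which drives the making of neutrophils, at 234 and 67.0 CPM (-1.80). Clusters 3 and 18 held 49.6% and 23.1% of control fibroblasts, while clusters 3, 5 and 11 held 32.1%, 28.4% and 23.6% of those of TSeL+L. Over clusters 3, 14 and 17 alone, given the same weight in both libraries, the medians were 0.62 for the collagen list, -0.52 for the cell cycle list, -0.023 for the antioxidant list and -0.082 for the recruiting factors. These clusters held 1204 of 1606 control and 2138 of 4532 TSeL+L fibroblasts.

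**Figure D3:**
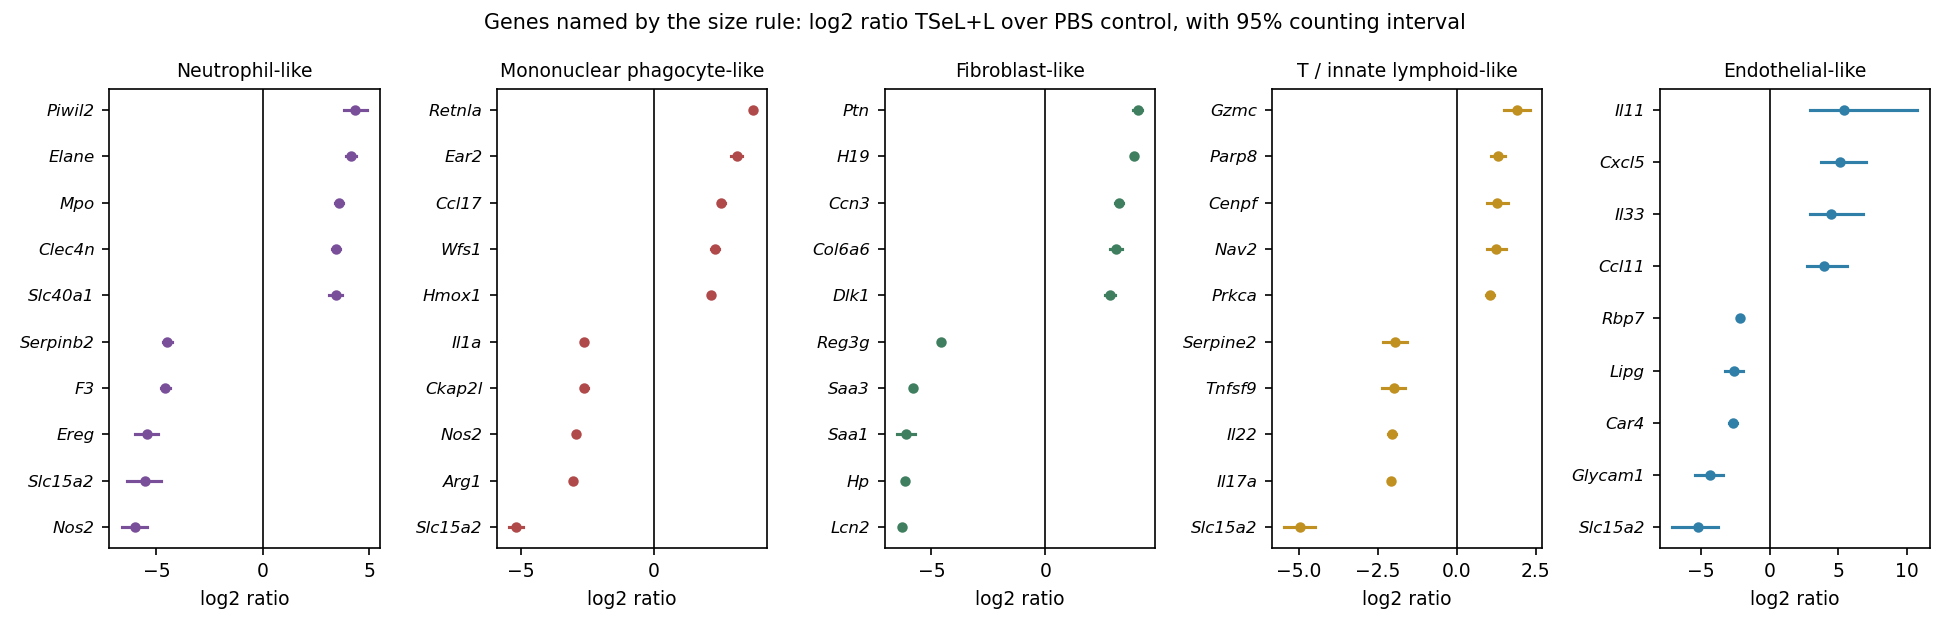
Log2 ratio (TSeL+L over PBS control, linear axis that differs between panels) of the genes named by the size rule and shown here, with exact 95% counting intervals as lines, and for neutrophils and phagocytes relative to the median gene of the class. Slc15a2 was among the lowest genes in 4 of the 5 classes, at -5.53, -5.18, -4.96 and -5.20.

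T cell-like and innate lymphoid-like cells of the TSeL+L library held less RNA of type 3 cytokines, the interleukin-17 family genes that call neutrophils to barrier tissue. Il17a was at 2232 CPM in the control and 526 CPM in TSeL+L (-2.09, -2.15 to -2.02), Il22, which acts on epithelial cells, at 501 and 122 CPM (-2.04, -2.18 to -1.91), and Il17f at 891 and 317 CPM (-1.49). Of 8 measured type 3 genes, 6 were lower and none higher (median -0.93, percentile 0), with 1 of them a marker of the class. Cluster 24, which expressed gamma-delta T cell genes and had Il17a as a leading gene, held 84.2% of the Il17a UMIs in the control and 74.1% in TSeL+L. It held 20.6% of the cells of the class in the control and 13.4% in TSeL+L. Over the whole class the gamma-delta marker Trdc stood at 358 and 195 CPM (-0.88).

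Type 2 genes were higher in 3 of 9 and lower in 1 (median 0.59, percentile 99.9), but only 5 of the 9 reached the free RNA guard and 5 were class markers. The median turned to -0.46 after a subtraction of free RNA and to -0.19 without doublet removal, and it holds Retnla, without a control UMI, at the floor. Il5, the eosinophil growth factor, stood at 12.4 and 46.7 CPM (1.91, in 8 and 39 cells), Il1rl1, the interleukin-33 receptor, at 57.5 and 138 CPM (1.26), and Areg, an epidermal growth factor family ligand, at 1127 and 486 CPM (-1.21). Cytotoxic and type 1 genes had 1 member higher and 1 lower of 12 (median -0.21, percentile 2.40, but 0.34 without the 3 class markers), with Gzmb, granzyme B, at 329.9 and 239 CPM (-0.47). Regulatory T cell genes had 2 lower and none higher of 10 (median -0.083, percentile 31.0), and checkpoint genes 2 lower and none higher of 7 (median -0.51, percentile 0.065), with the checkpoint receptor gene Lag3, on both lists, at 40.8 and 10.4 CPM (-1.97). Memory and residency genes had 2 higher and 1 lower of 11 (median 0.26, percentile 99.4), with Cd69, an early activation and residency marker, at 363 and 139 CPM (-1.39). Glycolysis and hypoxia genes were lower in 9 of 16 and higher in none (median -0.63, percentile 0), with Slc2a1, the glucose transporter GLUT1, at 113 and 47.7 CPM (-1.25). Antioxidant genes were higher in 5 of 18 and lower in none (median 0.27, percentile 99.8), and 7 of the 18 reached the free RNA guard.

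Slc15a2 was at 213 and 6.84 CPM (-4.96, -5.46 to -4.50), and the costimulatory ligand gene Tnfsf9 and the protease inhibitor gene Serpine2 were also among the lowest (-1.99 and -1.97). The highest by the size rule were Gzmc, a granzyme (22.2 and 82.5 CPM, 51.2% of its TSeL+L UMIs in 2 cells), Parp8 (71.9 and 177 CPM), Nav2 (46.2 and 110.0 CPM), Cenpf, a centromere protein of dividing cells (36.9 and 89.8 CPM), and Prkca, a protein kinase C (204 and 423 CPM). Their log2 ratios lay between 1.05 and 1.90, and that of Cenpf was 0.39 with equal weight per cell. With the 4 clusters of the class given the same weight in both libraries, the type 3 median was -0.56, the Il17a ratio -1.43 and the Il17f ratio -0.86, and after thinning the Il22 ratio was -1.34. RNA of other cell types was also counted in these cells, with the fibroblast gene Col1a1 at 86.3 and 449.5 CPM and the neutrophil gene S100a9 at 1053 and 91.2 CPM.

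Endothelial-like cells, 146 in the control and 279 in TSeL+L, gave fewer UMIs (653115 and 1525203) and wider intervals. Among the lowest genes by the size rule, Car4, a carbonic anhydrase of capillaries, was at 567 and 87.2 CPM (-2.70, -3.00 to -2.41), Rbp7, a retinol-binding protein, at 1868 and 409.8 CPM (-2.19, -2.33 to -2.05), and Lipg, endothelial lipase, at 110.2 and 18.4 CPM (-2.59). After thinning the ratios of Car4 and Rbp7 were -1.87 and -1.52. Angpt2, a destabilising ligand of the TEK receptor, was at 168 and 409 CPM (1.28, 0.99 to 1.59) and Pgf at 90.3 and 285 CPM (1.66). Hmox1 was at 88.8 and 694 CPM (2.97, 2.59 to 3.37, and 3.82 after thinning).

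The angiogenesis list moved both ways, with 4 genes higher and 5 lower of 12 (median -0.35, percentile 0.510, and -0.011 in cluster 21 alone). Antioxidant genes were higher in 8 of 18 and lower in none (median 0.32, percentile 99.5), including Srxn1, sulfiredoxin, at 13.8 and 72.8 CPM (2.40, 1.42 to 3.57, and 1.50 with equal weight per cell). Interferon-gamma response genes were higher in 5 of 10 and lower in 1 (median 0.53, percentile 98.8), with the chemokine Cxcl9 at 103 and 221 CPM (1.11), in 24 and 50 cells, a ratio that was 0.37 without doublet removal, under the 1.5-fold limit. MHC class I genes had none of 12 past the size limit (median 0.13, percentile 85.8, but -0.053 after thinning), and glycolysis and hypoxia genes had 1 higher and 3 lower of 16 (median -0.0041, percentile 49.6). Among the highest genes by the size rule were the secreted factors Cxcl5 (4 and 327 UMIs), Il11 (1 and 101 UMIs, log2 ratio 5.43 with an interval of 2.92 to 10.75), Il33 (3 and 158 UMIs, 4.50 with an interval of 2.92 to 6.79) and Ccl11 (5 and 182 UMIs). Their TSeL+L UMIs lay in 23 to 37 cells, and 2 cells held 49.5% of those of Cxcl5. The ratio was 0.94 for Il11 and 1.94 for Il33 after thinning, and that of Ccl11 went from 3.96 to 2.13 without doublet removal. The fibroblast gene Col1a1 stood at 103 and 889 CPM in the same class, and S100a9 at 4529 and 65.6 CPM. Among the lowest were Slc15a2 (63 and 4 UMIs, -5.20) and Glycam1, a ligand of L-selectin, whose 88 control UMIs all lay in 2 cells and whose ratio turned from -4.36 to 0.067 after thinning to 1000 UMIs per cell.

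Genes of dissociation and of the immediate early response, which handling of tissue can induce, were lower in 6 of 13 and higher in none in fibroblasts (median -0.53, percentile 0.0300). In T and innate lymphoid cells 4 of 13 were lower and none higher (median -0.52, percentile 0), and in endothelial cells 4 and none (median -0.33, percentile 1.07). In phagocytes 1 of 13 was lower and none higher (median -0.19, percentile 20.1), and in neutrophils 4 were lower and 1 higher relative to the median gene (median -0.14, percentile 85.2), and 7 higher and none lower on class totals (median 0.72).

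Slc15a2 was lower in TSeL+L in all 5 classes. Hmox1 was higher in 4 of them, and in neutrophils only before the ratio was set against the median gene. In the mm10 build, by the GENCODE vM21 annotation, Slc15a2 (ENSMUSG00000022899) is a protein-coding gene on the minus strand of chromosome 16 from 36750177 to 36784962, and Hmox1 (ENSMUSG00000005413) is a protein-coding gene on the plus strand of chromosome 8 from 75093621 to 75100589. Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46711998 to 46715700 and Retnla (ENSMUSG00000061100) on chromosome 16 from 48842551 to 48844461. Il17a (ENSMUSG00000025929) lies on chromosome 1 from 20730905 to 20734496, Nos2 (ENSMUSG00000020826) on chromosome 11 from 78920787 to 78960254 and H19 (ENSMUSG00000000031), a long non-coding RNA, on chromosome 7 from 142575529 to 142578143. In fibroblasts Slc15a2 was at 21.0 and 3.39 CPM (-2.63). The UMIs come from the 3' ends of transcripts and carry no information on exon use.

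**Figure D4:**
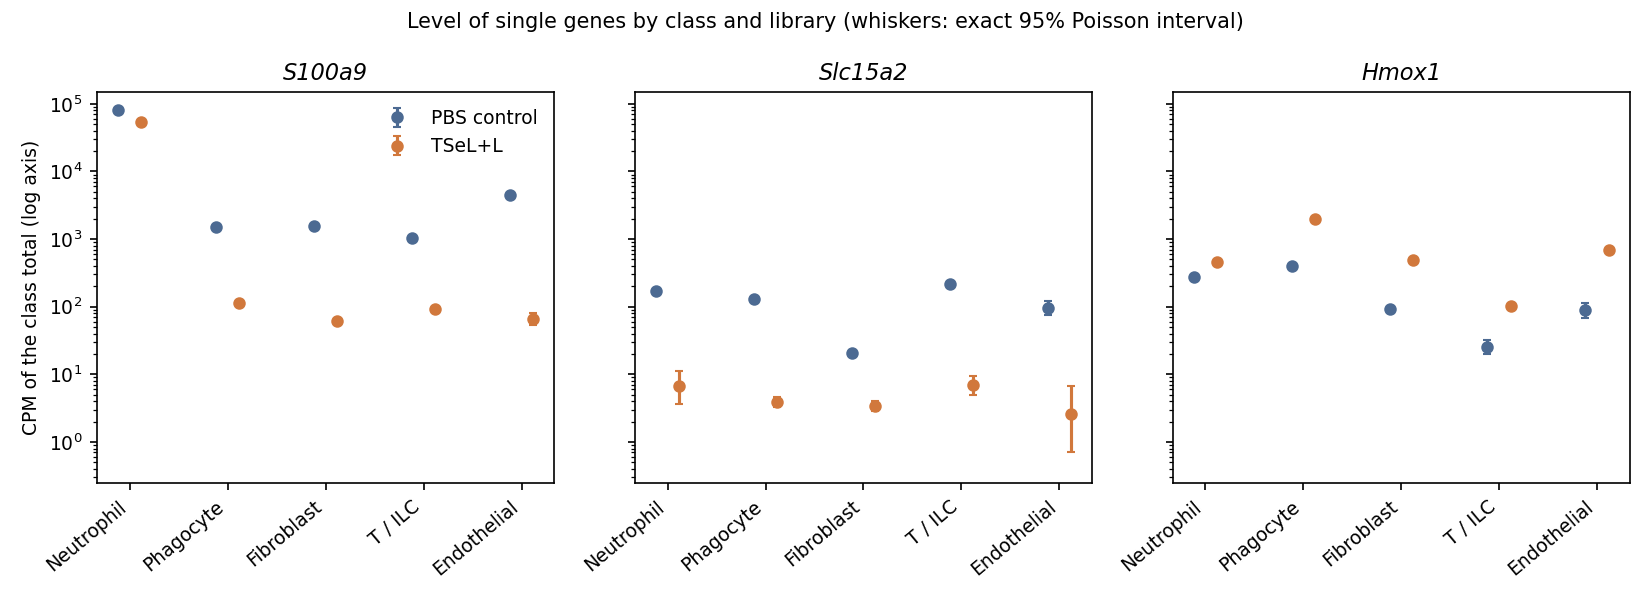
CPM of the class total (log axis) for S100a9, Slc15a2 and Hmox1 in each class of the PBS control and TSeL+L libraries, with exact 95% Poisson intervals. S100a9, a neutrophil gene, stood at 1053 and 91.2 CPM in T and innate lymphoid cells, and Slc15a2 was lower in TSeL+L in each class. The CPM of Hmox1 was higher in each, though in neutrophils the ratio was -0.14 relative to the median gene.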

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

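All tests in this part were chosen after the result they bear on was seen. The clusters that stayed unnamed lie outside the class comparisons and took a larger share of TSeL+L cells than of control cells, 23.7% against 7.08%. Cluster 2 held 17.8% of TSeL+L and 0.528% of control cells with a median of 850 UMIs, and its leading genes were Cdk8, Gm48099, Veph1 and Cmss1. Cluster 10 held 4.61% and 2.94%, and led with Cdk8, Gm42418 and the macrophage genes Pf4 and Ccl8. Cluster 25 held 0.991% and 0.243% and led with neural genes, among them the Schwann cell marker Cdh19, while its best score was for fibroblasts, as in clusters 2, 32 and 35. Cluster 19, also unnamed, held 3.12% of control and 0.0313% of TSeL+L cells. Clusters 32 and 35 held 0.125% and 0.0878% of TSeL+L cells and 0 and 1 control cells.

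The share of neutrophils was 5.26-fold lower in the TSeL+L library. It would be 31.8% if every unnamed TSeL+L cell were a neutrophil, still under the control interval. A loss to the unnamed clusters thus does not account for all of the difference. Marker scores argue against it for part of the difference in clusters 2 and 10, which held 17.8% and 4.61% of TSeL+L cells. Cluster 2 scored 4.18 for fibroblasts, with macrophages next at 2.38. Cluster 10 scored 3.15 for macrophages, with neutrophils next at 0.44. In cluster 19 neutrophils came close, at 2.98 against 3.16 for fibroblasts, but it held 5 TSeL+L cells. Neutrophil RNA in T cells, as a fraction of the library level, was 1.57 times as high in TSeL+L as in the control (median of S100a8, S100a9 and Retnlg). Neutrophils of usual RNA content that were present but not called as cells would need at least 5.26, the fall in cell share. They would need more by the library level itself. It fell from 19724 to 818 CPM for S100a8, from 23798 to 1312 CPM for S100a9 and from 2894 to 30.2 CPM for Retnlg. The fraction of the library level was lower in TSeL+L endothelial cells (0.272 times for S100a8 and 0.263 for S100a9) and fibroblasts (0.931 and 0.723), which runs against uncalled neutrophils. In phagocytes it was 2.49 times for S100a8, 1.35 for S100a9 and 0.597 for Retnlg. Retnlg was at 3.04 (interval 1.77 to 4.91) in T cells and 2.91 in fibroblasts, and doublets with neutrophils may hold part of this RNA. All these ratios, up to the highest interval bound of 4.91, were under 5.26. That argues against uncalled neutrophils of usual RNA content as the account of the whole fall. For a part of the fall they cannot be told apart from a lower number, since the fraction was higher in TSeL+L T cells. Neutrophils with little RNA stay open as well: 15.02% of those of TSeL+L and 1.91% of those of the control had fewer than 1000 UMIs, and losses under the limit of the deposited barcodes cannot be told apart from a lower number. The treatment, the single animal or pool behind each library and the dissociation stay open too and were not tested.

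Slc15a2 was lower in all 5 compared classes. In T cells free RNA of neutrophils is argued against, since control T cells held 1.27 times the level of control neutrophils (interval 1.16 to 1.38). Free RNA of phagocytes is argued against in T cells as well, since control T cells held a higher CPM of Slc15a2 than control phagocytes. Free RNA of neutrophils or phagocytes in the other classes was not tested. The 19 other measured genes within 1 Mb on chromosome 16, without the stefin genes that neutrophils express, were looked at in T cells. Relative to the median gene of that class, their median absolute log2 ratio was 0.25 against 0.28 for all measured genes. These neighbours were thus not displaced more than other genes. A variant of the segment that leaves their RNA unchanged cannot be excluded by these values. A variant of the gene alone and an effect of treatment or infection were not tested and stay open.

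Hmox1 was higher in phagocytes, fibroblasts, T cells and endothelial cells of TSeL+L, while of the 18 antioxidant genes 7 were higher in phagocytes, 11 in neutrophils, 6 in fibroblasts, 5 in T cells and 8 in endothelial cells (medians 0.52, 0.64, 0.070, 0.27 and 0.32). The values of phagocytes and neutrophils are relative to the median gene, and on class totals 10 and 16 genes were higher there. As a fraction of the phagocyte level, Hmox1 in TSeL+L fibroblasts was 7.93 times, and in endothelial cells 5.00 times, the highest of the phagocyte markers C1qa, C1qb, C1qc and Csf1r, which argues against free phagocyte RNA there. In T cells it was 1.43 times, a level that free RNA could account for. On class totals, with the same cluster weights in both libraries, the phagocyte list median was 0.53 on the log2 scale against 0.63 with clusters summed. A different mix of these clusters does not account for it, while a different mix of cells within clusters was not tested. Haemoglobin RNA was also higher in TSeL+L phagocytes and in the whole library (Hba-a1 at 0.965 and 11.2 CPM), so a response to haem was not tested and stays open beside an effect of the treatment, which 1 library per group cannot test.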

How the results depend on the processing

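No paired analysis was possible because each group has 1 library and the results come from no test. Alternatives on equal cluster weights, on naming every cluster and on leaving out class markers were chosen after the data were seen; the others were planned. Of 81 share differences under alternatives 75 kept their sign and 5 were 0 because no cluster bore the name, of 468 list medians 448, and of 1665 ratios of named genes 1652. Where a value below moved, the cause was not tested. Control endothelial cells held 653115 UMIs, and thinning left out 193 TSeL+L neutrophils.

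Share differences are TSeL+L minus control in percentage points. With at least 1000 UMIs and 500 genes, neutrophils went from -34.3 to -35.9, fibroblasts from 15.4 to 19.8, T and innate lymphoid cells from 3.92 to 4.96, and phagocytes from -2.82 to 1.94, a change of sign. Neutrophils stood at -31.9 with all barcodes of 200 genes and at -32.6 with no doublet removal. Phagocytes stood at -1.53 with no doublet removal, -1.27 at Leiden resolution 2.0, -0.824 with genes scaled within libraries, -4.19 with 15 principal components and -1.14 with every cluster named. Fibroblasts stood at 17.7 at resolution 2.0 and 30.5 with every cluster named. The endothelial difference, 0.564, ranged from 0.438 to 0.723.

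List medians here are log2 ratios of class totals. The neutrophil granule list went from 1.64 to 0.78 with the median-of-ratios scale, 1.22 without the 50 most abundant genes, 0.77 with equal weight per cell, 0.86 thinned, 1.20 with a minimum of 100 UMIs and -1.13 in cluster 6 alone, a value from 2 and 11 UMIs that gives no direction. The phagocyte inflammatory list went from -0.90 to -1.01 with the median-of-ratios scale, -0.83 at resolution 2.0, -0.86 after free RNA subtraction and -0.66 with equal cluster weights. With the median-of-ratios scale and with equal cluster weights, the alternative activation list went from 0.53 to 0.42 and 0.29, and the antioxidant list from 0.63 to 0.52 and 0.53. The fibroblast collagen list went from 0.80 to 0.76 with both other totals, 0.75 with equal weight per cell, 0.62 with equal cluster weights and 0.75 without class markers. The type 3 list went from -0.93 to -0.56 with equal cluster weights. The angiogenesis list stayed within its wide interval, from -0.65 to -0.011.

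Other signs turned as follows. With equal cluster weights, values became -3.59 for Elane, -5.18 for Mpo and -2.59 for Prtn3 in neutrophils, from 1 and 1, 0 and 1, and 1 and 2 UMIs in cluster 6, so none of the 3 gives a direction and that of Mpo rests on the floor of 3 UMIs, -0.52 for Il12b in phagocytes, and 0.017 for Mmp12, -0.32 for Ereg, -0.082 for Cxcl2 and -0.16 for Cxcl1 in fibroblasts. The median of oxygen radical genes in neutrophils, 0.081, became -0.78 with the median-of-ratios scale, -0.34 without the 50 most abundant genes, -0.18 with equal weight per cell, -0.15 thinned and -0.14 in cluster 6. The fibroblast antioxidant median became -0.023 and that of the neutrophil-recruiting factors -0.082 (-0.0025 with no doublet removal). In neutrophils Clec4d became -0.059 with the median-of-ratios scale, and the pattern recognition median -0.44 with that scale, -0.0034 without the 50 most abundant genes and -0.20 in cluster 6. Retnla in T cells became -1.18 after free RNA subtraction, Glycam1 in endothelial cells 0.067 after thinning, and B2m there -0.064 with equal weight per cell and -0.066 after thinning. The type 2 median of T cells, whose interval included 0, became -0.46 after free RNA subtraction and -0.19 with no doublet removal, and their cytotoxic median 0.34 without class markers. In endothelial cells the MHC class I median became -0.053 after thinning, and the glycolysis median, -0.0041, became 0.013 with the median-of-ratios scale, 0.057 with equal weight per cell, 0.080 after free RNA subtraction and 0.011 in cluster 21.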

Other observations

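All tests in this part were chosen after the data were seen. Several imprinted genes differed in fibroblast-like cells between the libraries, in both directions. They come from a list of 20 well-known imprinted genes written after H19 and Dlk1, 2 of its members, had been seen, so it is no test of imprinted genes as a group. Of 19 measured, 8 were higher, 5 lower and 6 neither. The growth factor gene Igf2 stood at 2.04 and 23.8 CPM (log2 ratio 3.55, interval 3.11 to 4.02), Cdkn1c, an inhibitor of the cell cycle, at 62.5 and 201 CPM (1.69), and Mest at 20.1 and 67.8 CPM (1.75), while Peg3 stood at 126 and 77.2 CPM (-0.70) and Peg10 at 18.5 and 10.5 CPM (-0.81). H19 was higher within each shared cluster, at 64.4 and 397 CPM in cluster 3, 30.9 and 316 CPM in cluster 14 and 9.88 and 285 CPM in cluster 17. Peg3 had log2 ratios of -0.26, -0.25 and -0.68 in these clusters and Peg10 of -0.75, 0.21 and 1.67, so the lower Peg10 was not kept within clusters 14 and 17, and Peg3 was under the 1.5-fold limit in clusters 3 and 14 (interval -0.65 to 0.14 in cluster 14). Mest had ratios of 0.78, 0.50 (interval -0.29 to 1.31) and 2.60 there and Cdkn1c of 1.68, 0.98 and 1.03. Igf2 had a ratio of 2.68 in cluster 3 and of 2.76 in cluster 14, the latter from 4 and 28 UMIs.

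Differences of Saa3, Hp, Lcn2, Il17a and Il22 were also present within shared clusters. Saa3 stood at 8821 and 481 CPM in fibroblast cluster 3, at 17007 and 82.8 CPM in cluster 14 and at 34373 and 1370.1 CPM in cluster 17, and Hp and Lcn2 were lower in TSeL+L in all 3 clusters. In cluster 24, with 104 control and 171 TSeL+L cells, Il17a stood at 10757 and 3854 CPM (-1.48, -1.55 to -1.41) and Il22 at 1778 and 452 CPM (-1.98), while Trdc, the constant region of the delta chain, stood at 2016 and 1885 CPM (-0.096, -0.22 to 0.032).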
